A study of Homo sapiens with 2 samples.

How the data were processed

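RNA was measured in 2 libraries from H1993, an established lung adenocarcinoma cell line in which the gene of the receptor tyrosine kinase MET is amplified. One library came from the parental line and 1 from a derivative selected for resistance to PHA665752, a small-molecule inhibitor of the MET kinase. Per the labels' protocols, the derivative was selected in drug raised from 1 nM to 1 µM, kept in 1 µM, and grown without drug for 1 week before experiments. The sample labels also give DMSO as the treatment of the parental library and PHA665752 as that of the resistant one, and do not say whether drug was present when RNA was taken. Per the labels' protocols, RNA was extracted with TRIzol and chloroform and the libraries were made with a TruSeq kit.

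The authors deposited a table of raw counts per gene symbol, named as raw data per the file headers, with whole numbers for 18944 genes in both libraries. Per the submitters' processing notes, reads were checked with FastQC and aligned with STAR, with no version given. The same notes name both GRCh38 and hg19 as genome builds without saying which was used for what, so no coordinates are given here. The counting program, its annotation, its strand setting and its treatment of reads that fit several genes are not stated. Genes with near-identical copies and genes that overlap are therefore uncertain where named. The table has 0 mitochondrially encoded genes, so the share of mitochondrial RNA is unknown.

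The deposited table also holds 1 normalized log2 value per gene and library, per the file headers. The method behind them is not stated and was not worked out here. With 0 counts, 5 genes in the parental and 7 in the resistant library have a deposited log2 value above 0. The log2 values entered only as an alternative, and every value below comes from the counts unless it is named otherwise. A difference of 1 in them was out of reach for a gene under 1 in both libraries, unless a value fell below 0. AXL, at 0.123 and 0.784, is such a gene. Where such a gene did not pass with the deposited log2 values, this does not bear on its call from the counts.

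The counts summed to 16723181 in the parental and 17086748 in the resistant library. Libraries were scaled with edgeR 4.0.16 by the trimmed mean of M-values (TMM) in R 4.3.3, which gave effective sizes of 16834058 and 16974207, and all CPM values refer to these sizes. A gene was tested when it had at least 1 CPM in at least 1 library. A gene under 1 CPM in 1 library was therefore tested only through the other. For such genes the filter fixed the direction of the difference, though not its size. The log2 ratio is resistant over parental, with 0.5 added to each count. Its exact 95% interval (conditional binomial, Clopper-Pearson, scipy 1.17.1) uses the counts without that addition and covers counting error only. Reads are not independent molecules, so the intervals are, if anything, too narrow. A gene was called at least 2-fold higher or lower when its log2 ratio was 1 or more in size and the interval excluded 0. A count of 0 allows up to 3 counts, which is 0.178 CPM in the parental and 0.177 CPM in the resistant library. Folds against a count of 0, given as "at least", set the observed count of the other library against these 3 counts. They leave out the counting error of that other library, so they lie beyond the near end of the exact interval. For NRG2, at least 10.3-fold higher, that end was a log2 ratio of 2.97.

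With 1 library per group there is no replicate check of any difference and no test or p-value across genes. Every statement describes these 2 libraries. The question behind the comparison is which genes differ between the MET-amplified line and its drug-resistant derivative.

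For 44 gene lists fixed before the data were examined, the measured members, the members past 2-fold in each direction and the median log2 ratio were taken. Each median's percentile among 10000 random lists of the same size, matched on mean expression in 20 bins (seed 1), describes where the list stands among genes of like abundance. It is not a test. Lists with under 5 measured members have no median. Older symbols were matched through RefSeq synonyms. Setting genes with 0 counts to their bound left the medians of 37 lists as they were. Gene order and chromosomes came from the RefSeq annotation of assembly GRCh38.p14, which placed 18849 of the 18944 symbols. The running median of the log2 ratio over 25 consecutive tested genes was computed along each chromosome, and windows at 0.8 or more in size were listed.

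The genes named in the report follow a rule fixed before the data were examined. It takes MET and AURKB, the kinase in the series title. It adds, among genes of at least 10 CPM in at least 1 library, the 15 with the highest lower bound and the 15 with the lowest upper bound of the interval, leaving out ribosomal RNA, mitochondrial, small nucleolar and microRNA genes, clone-style symbols, XIST and Y-linked genes. It further takes all measured members of the MET, Aurora, ERBB and BCL2 lists and, of every other list, up to 4 members with the largest ratios past 2-fold plus the most abundant member, taken by the mean CPM of both libraries. A few names that the rule takes are left out of the text and not replaced. Where a count is 5 or fewer, the remaining members are mostly named too, and those names, like the gene families and blocks in the closing section, were chosen after their values were seen.

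The ratio, interval, calling and list procedures were tested on simulated data: Poisson counts for the 18944 genes at the real library sizes, with 200 genes changed. The changed genes were drawn only from those of at least 2 CPM averaged over both libraries. Recovery of scarcer genes was therefore not simulated. Of the genes changed 3-fold, 100% passed the 2-fold rule, as did 100% of those changed 6-fold. Among unchanged tested genes 0.25% passed, and 95.25% of the intervals held the true ratio. These figures hold for counting noise alone, without biological variation. Alternatives covered the scaling (total counts, DESeq2 1.42.0 size factors, upper quartile), the filter, the size rule, the added count, thinning of the deeper library, the bins and the window. The deposited log2 values, a correction for GC content and transcript length (statsmodels 0.14.6, GENCODE v29 transcripts), a window of 9 genes and 2 checks on the lists were added after the data were seen.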

Results

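Gene expression was measured by RNA sequencing in H1993 cells, a MET-amplified human lung cancer line, and in a derivative selected for growth in the MET inhibitor PHA665752. There was 1 library per group, with 16723181 counts in the parental and 17086748 in the resistant library. At least 1 count was found for 14205 genes in the parental and 14655 in the resistant library. The 10 most abundant genes took 3.58% of the counts (exact 95% interval 3.57 to 3.59%) in the parental library and 3.83% (3.82 to 3.84%) in the resistant one. The 37 ribosomal protein genes of the fixed list, a part of all such genes, took 3.43% (3.42 to 3.44%) and 3.44% (3.43 to 3.45%). By these measures depth and composition were close, and all intervals here and below cover counting error only.

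MET, the target of the drug, was the most abundant gene of the parental library at 4859 CPM and still ranked 6 in the resistant library at 3054 CPM. Its level was 1.59-fold lower in the resistant library (95% counting interval 1.57 to 1.61), short of the 2-fold rule. AURKB, the mitotic kinase named in the series title, was 1.73-fold lower (1.57 to 1.92), at 61.7 CPM in the parental and 35.6 CPM in the resistant library, also short of the rule. No replicate measures how much either gene varies between cultures.

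Of 12245 tested genes, 1480 (12.1%) were at least 2-fold higher and 1015 (8.29%) at least 2-fold lower in the resistant library, and 9750 passed neither. With the deposited log2 values, 926 and 591 genes differed by 1 or more, and stricter size rules gave 1097 and 655 (whole interval beyond 2-fold) or 774 and 359 (4-fold). The median log2 ratio was 0.00, with quartiles of -0.39 and 0.43. The whole interval lay beyond 10-fold for 253 genes on the higher and 88 on the lower side. At 0 counts in the parental library, 26 genes reached 10 CPM or more in the resistant one, and 8 genes showed the reverse.

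**Figure D1:**
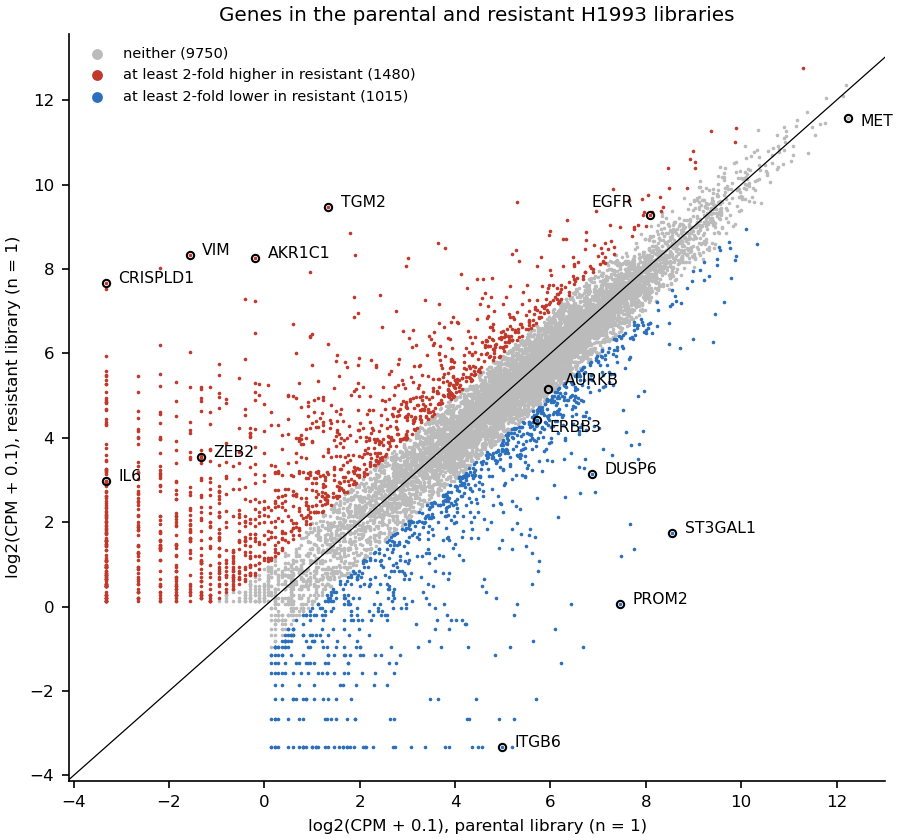
Scaled expression of the 12245 tested genes in the parental (x axis) and resistant (y axis) library, as log2 of CPM plus 0.1, with 1 library per group. Red points are the 1480 genes at least 2-fold higher and blue points the 1015 at least 2-fold lower in the resistant library, the line marks equal expression, and MET lies near the top just under it.

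The genes with the highest lower bounds included the mesenchymal intermediate filament gene VIM, at 0.238 CPM in the parental and 322 CPM in the resistant library. EPB41L3, a membrane cytoskeleton gene, stood at 0.119 and 260 CPM. The protein crosslinking enzyme gene TGM2 was 289-fold higher (213 to 403) and reached 704 CPM. The aldo-keto reductase gene AKR1C1, which shares near-identical sequence with AKR1C2 and AKR1C3, was 394-fold higher (230 to 740). BICC1, an RNA-binding protein gene, had 2 counts in the parental and 1250 in the resistant library. The remaining 10 had 0 counts in the parental library. CRISPLD1 was at least 1135-fold higher, the collagen-binding receptor gene ANTXR1 at least 1035-fold and the phosphodiesterase gene PDE3A at least 342-fold. COL25A1, the growth factor gene FGF2, TMEM178B, the branched-chain aminotransferase gene BCAT1, HSD17B2, the retinoic acid synthesis gene ALDH1A2 and IGFBP7 were at least 190-fold to 268-fold higher.

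Among the 15 genes with the lowest upper bounds, 7 had 0 counts in the resistant library. DIAPH2 was at least 205-fold lower, the epithelial integrin gene ITGB6 at least 178-fold and the glycosyltransferase gene GALNT13 at least 133-fold. ZNF516, the keratin gene KRT4, FAM110C and the neuronal RNA-binding protein gene ELAVL2 were at least 78.0-fold to 125-fold lower. The receptor gene ADGRF1 had 102 CPM in the parental and 0.412 CPM in the resistant library. The epithelial membrane gene PROM2 was 187-fold lower (115 to 328), the annexin gene ANXA10 87.1-fold lower (64.3 to 121) and the sialyltransferase gene ST3GAL1 116-fold lower (88.9 to 154). The growth factor gene IGF2 was 254-fold lower (109 to 784). The phosphatase gene PTPRR and the transcription factor genes SALL1 and SOX21 had 878, 632 and 511 counts in the parental library, against 2, 1 and 1.

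Genes around the MET receptor stayed within 2-fold for 18 of 21 measured members. The 3 exceptions were lower in the resistant library: HPN and ST14, proteases that activate the MET ligand, with log2 ratios of -2.59 and -1.46, and the integrin gene ITGB4 at -1.49. The gene of the ligand, HGF, had 0 counts in both libraries. PTPN11 (-0.69) and CD44 (-0.64) had ratios below 0 as MET did, with PLXNB2 (-0.46), LRIG1 (-0.45), GAB1 (-0.43), RANBP10 (-0.32), CBLB (-0.25), RANBP9 (-0.20) and CBL (-0.16). PTPRJ (0.80), SPINT1 (0.39), SHC1 (0.25), PLXNB1 (0.13) and GRB2 (0.12) had ratios above 0. PTPN1 (-0.07), ERRFI1 (0.01) and SPINT2 (0.01) differed little. The list's median was -0.25, at percentile 4.86 of the matched random lists.

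Genes beside MET on chromosome 7 had a median log2 ratio of -0.34 over 14 measured members (percentile 2.53), with 10 ratios below 0. The caveolin gene CAV1 was 3.16-fold lower (3.06 to 3.27) and MDFIC 2.16-fold lower (2.01 to 2.31). CAV2, the most abundant of them (here and below, by the mean CPM of both libraries), was at 1142 CPM in the parental and 777 CPM in the resistant library. KCND2, CTTNBP2 and CPED1 were higher, from 0, 0 and 10 counts to 130, 46 and 179, with CTTNBP2 at 0.54 with the deposited log2 values. The symbol NAA38 in this list now belongs to a gene on another chromosome, and the median was -0.56 both without it and with at least 5 CPM in at least 1 library.

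Aurora kinase and chromosomal passenger genes were close between the libraries, with 0 of 11 measured members past 2-fold and a median of -0.07 (percentile 41.6). Their median absolute log2 ratio of 0.07 lay at percentile 0.08, so these genes differed less than almost all matched lists. After AURKB itself, the survivin gene BIRC5 differed most, at -0.53. KIF20A (-0.24), BORA (-0.22) and BUB1 (-0.20) followed. AURKA (-0.07), GSG2 (-0.07), INCENP (-0.01), KIF4A (0.02), TPX2 (0.04) and CDCA8 (0.04) were all within 0.07 of 0. Of 42 G1/S genes only POLA1 passed 2-fold (-1.03, or -0.97 with the deposited log2 values), and the median was -0.16 (percentile 6.81), with MCM4 the most abundant at -0.69. Of 52 G2/M genes only the lamin B receptor gene LBR passed (-1.33), with a median of -0.10 (percentile 18.3) and TUBB4B the most abundant at -0.15.

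Receptors and ligands of the ERBB family diverged in both directions. EGFR was 2.29-fold higher in the resistant library (2.21 to 2.37) and reached 620 CPM. Of the ligand genes, NRG1 was 4.09-fold higher (3.43 to 4.90), EPGN 4.77-fold (4.23 to 5.39) and NRG4 4.15-fold (2.82 to 6.26), while NRG2, at 0 and 31 counts, was at least 10.3-fold higher. ERBB3, the partner receptor of ERBB2, was 2.45-fold lower (2.17 to 2.78). The EGFR ligand genes TGFA and AREG were 4.60-fold (4.12 to 5.15) and 2.45-fold (1.45 to 4.29) lower. ERBB2 (-0.60), EREG (-0.37), BTC (0.82) and HBEGF (0.87) did not pass. Nor did NRG2 (0.56) and AREG (-0.82) with the deposited log2 values. Over 12 measured members, 5 were higher and 3 lower, with a median of 0.85 (percentile 99.9).

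Among 22 other receptor tyrosine kinases, 3 were higher and 6 lower, with a median of -0.30 (percentile 2.55), or -0.46 with at least 5 CPM. The higher ones, AXL, MERTK and FLT4, remained scarce, at 3.06, 2.53 and 2.65 CPM in the resistant library. They were under 1 CPM in the parental library and were measured only through the resistant one. Their deposited log2 values differed by 0.66, 0.62 and 0.59. These values were under 1 in both libraries (0.784, 0.777 and 0.642 in the resistant one), so a difference of 1 was out of reach. The lower ones included MST1R, which encodes the receptor closest to MET, at -2.38, and also ROR1 (-2.10), DDR1 (-1.39) and EPHB6 (-1.93), named after their values were seen. EPHB4, the most abundant, was at -0.33. Outputs and feedback inhibitors of the ERK pathway had 4 of 20 members lower and 0 higher, with a median of -0.48 (percentile 0.05). The other 16 passed neither way, and 5 ratios were above 0. The ERK phosphatase gene DUSP6 was 13.3-fold lower (11.2 to 15.8), SPRY1 3.39-fold (2.89 to 3.99), FOS 2.46-fold (1.91 to 3.19), and PHLDA1, the most abundant member, was at -1.27.

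**Figure D2:**
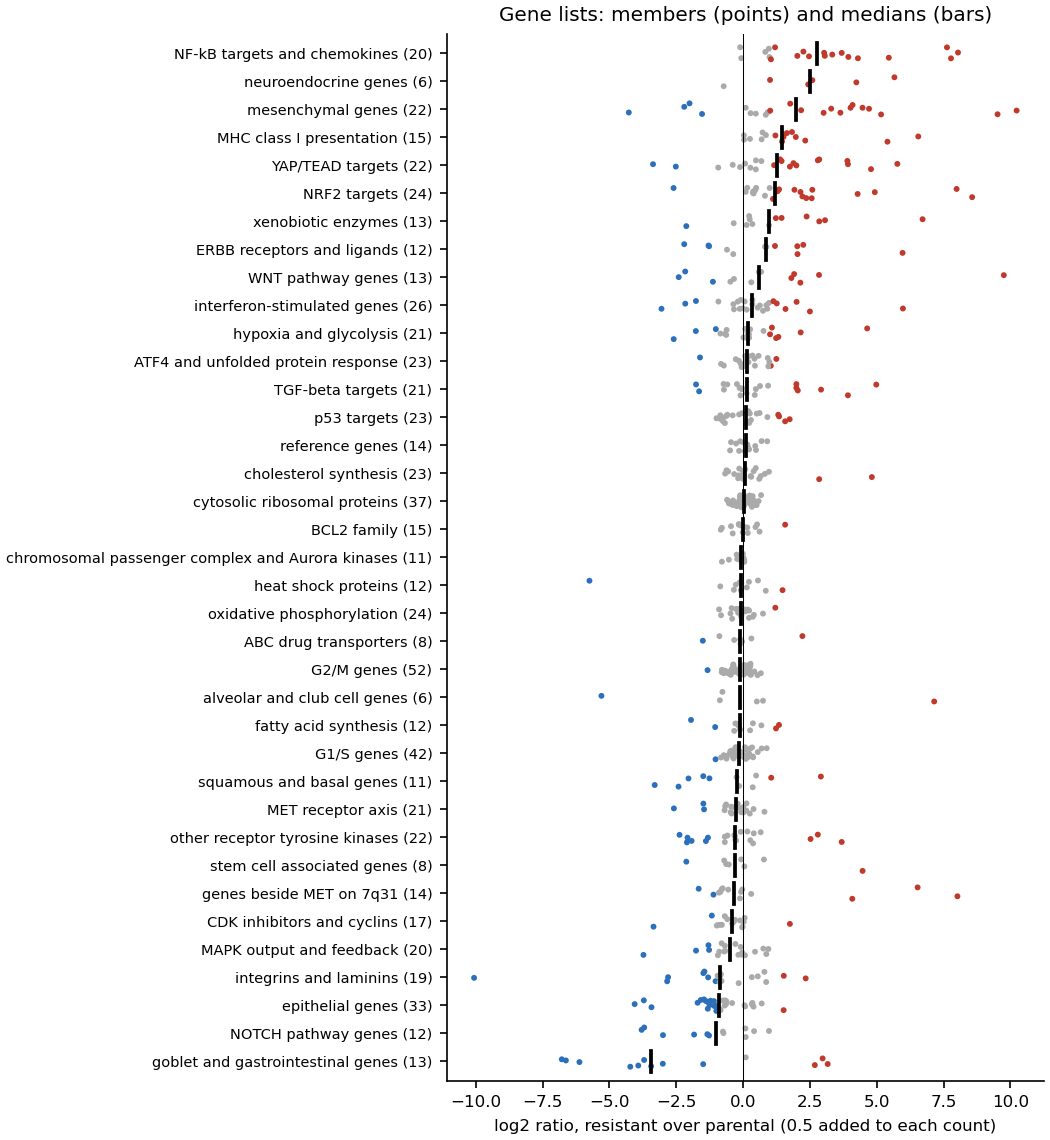
Log2 ratio of resistant over parental for each measured member (points) of the 37 lists with at least 5 measured members, with the list median as a black bar and the number of members in parentheses. Red and blue points are members at least 2-fold higher or lower, and medians run from -3.44 for goblet and gastrointestinal genes to 2.75 for NF-kB targets and chemokines.

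The median log2 ratio was below 0 for epithelial genes and above 0 for mesenchymal genes, with members in both directions in each list. Of 33 epithelial genes, 16 were at least 2-fold lower and 1, MUC1 (1.52), was higher, with a median of -0.91 (percentile 0). LAD1 was 10.8-fold lower (9.18 to 12.7) and the regulator gene OVOL1 3.26-fold (2.70 to 3.96), and PRSS8 had 19 and 1 counts (-0.66 with the deposited log2 values). The keratin gene KRT8, the most abundant member, was not lower, at 2666 CPM in the parental and 3394 CPM in the resistant library. Of 22 measured mesenchymal genes, 13 were higher and 4 lower, with a median of 1.97 (percentile 100), which was 3.01 with at least 5 CPM and 1.21 with the deposited log2 values. Beside VIM, FSTL1 was at 13.7 and 359 CPM, the transcription factor gene ZEB2 was 39.3-fold higher (16.6 to 122) and the collagen gene COL5A1 at least 122-fold. With the deposited log2 values, ZEB2 and COL5A1 differed by 1.235 and 1.823. The 4 lower members were TNC (-2.00), SNAI2 (-4.27), TAGLN (-2.20, or -0.83 with the deposited log2 values) and TPM2 (-1.53).

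Integrin and laminin genes had a median of -0.86 over 19 members (percentile 0), with 7 lower and 2 higher. Beside ITGB6, the laminin receptor gene ITGA3 was at -2.84 and LAMA4 at -2.81. ITGA1 (2.34) and LAMB3 (1.52) were higher, and ITGB1, the most abundant, was at -0.17. NOTCH pathway genes were lower for 6 of 12 members and higher for 0, with a median of -1.01 (percentile 0). The receptor gene NOTCH3 was 13.9-fold lower (12.4 to 15.7) and its target HEY1 13.1-fold (9.92 to 17.6), with LFNG at -3.00 and the ligand gene JAG1 at -1.83. NOTCH2, the most abundant by the mean of both libraries though not in the parental one, was at 0.09.

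Targets of YAP and TEAD were higher for 12 of 22 members and lower for 2, with a median of 1.27 (percentile 100), or 0.69 with at least 5 CPM and 0.66 with the deposited log2 values. NUAK2 was 28.0-fold higher (19.7 to 41.2) and ANKRD1 15.2-fold (10.7 to 22.2), CTGF had 3 and 53 counts, and RBMS3 was at least 8.93-fold higher, though at 0.52 with the deposited log2 values. MYOF, the most abundant, was at -0.39. The 2 lower members were F3 (-3.37) and ASAP1 (-2.52). TGF-beta targets had 6 higher and 2 lower members of 21, and the median of 0.13, or 0.28 with at least 5 CPM, did not stand apart (percentile 84.3). The higher ones included TGFBI (2.92), INHBA (2.05) and IGFBP3 (1.99), the most abundant. The lower ones were ID2 (-1.76) and PMEPA1 (-1.64).

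NF-kB targets and chemokines showed the highest median of all lists, 2.75 over 20 members (percentile 100), with 15 higher and 0 lower, and 1.47 with the deposited log2 values. IL6, SAA1 and CXCL1 had 0 counts in the parental library and 132, 110 and 99 in the resistant one, and IL32 had 4 and 198. All of these were under 1 CPM in the parental library and were measured only through the resistant one. CXCL1 and SAA1 have near-identical paralogs, so their split among copies is uncertain. TNFAIP2, the most abundant, was at -0.07. All 15 measured genes of MHC class I presentation had ratios above 0, and 9 passed 2-fold, with a median of 1.46 (percentile 100). The immunoproteasome genes PSMB9 and PSMB8 were 103-fold (43.9 to 319) and 43.8-fold (25.4 to 82.8) higher, TAP1 was at 1.97, ERAP2 at 2.33 and B2M, the most abundant, at 0.69. MHC class II genes had 0 measured members. Interferon-stimulated genes split, with 6 higher and 3 lower of 26 and a median of 0.35 (percentile 96.0), or 0.20 with the deposited log2 values. IFIT3, with 3 and 222 counts, and OAS3, with 216 and 1234, were higher and OAS1 (-3.05) and IFI44L (-2.16) were lower, with IFIT1 (-1.76) the third, while LGALS3BP, the most abundant, was at 0.14. With the deposited log2 values, 4 were higher and 1 lower, and IFI44L (-0.83) and IFIT1 (-0.83) did not pass.

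Targets of NRF2, the transcription factor of the oxidative stress response, were higher for 13 of 24 members, with a median of 1.20 (percentile 100). AKR1C1, AKR1C3 (2 and 638 counts), AKR1B10 (log2 ratio 4.93) and AKR1C2 (4.28) led them. The thioredoxin reductase gene TXNRD1 was 3.79-fold higher (3.71 to 3.87) and reached 2485 CPM. GPX2 (-2.60) was the 1 lower member. Another 10 passed neither way, among them GCLC (0.10) and GCLM (0.15), named after their values were seen. Xenobiotic enzymes had 6 higher and 1 lower of 13, with a median of 0.97 (percentile 99.98). ALDH3A1 was 8.39-fold higher (7.27 to 9.72), AHRR was at 2.38 and UGT1A6 at 2.85, and GSTM3 had 2 and 264 counts. GSTM3 and UGT1A6 share sequence with related genes. ALDH3A2, the most abundant, was at 0.97, and ALDH1A3 (-2.12) was the lower member. Of 8 measured ABC drug transporters, ABCC2 was higher (2.22) and ABCC5 lower (-1.51), and ABCG2, the most abundant, was at -0.10, which was also the list median (percentile 35.4), or -0.06 with the deposited log2 values.

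Regulators of apoptosis in the BCL2 family had 1 of 15 members past 2-fold, a median absolute log2 ratio of 0.39, which is ordinary for genes of like abundance (percentile 34.8), and a median of -0.01 (percentile 49.6), which was 0.04 with at least 5 CPM and 0.03 with the deposited log2 values. That member was BBC3, at 17 and 52 counts, and at 0.78 with the deposited log2 values. BAK1 (-0.84), the BIM gene BCL2L11 (-0.79), MCL1 (-0.39), BIK (-0.45), BOK (-0.16), BMF (-0.16), BCL2L1 (-0.09) and HRK (-0.01) had ratios below 0. BAX (0.62), PMAIP1 (0.52), BID (0.47), BCL2 (0.18), BCL2L2 (0.16) and BAD (0.04) had ratios above 0. Targets of p53 had 4 of 23 members higher, TP53INP1 (1.74), BBC3, TP53I3 (1.35) and FAS (1.31), and MDM2, the most abundant, at -0.84, with a median of 0.12 (percentile 72.1), or -0.04 with at least 5 CPM. Of these 4 only FAS passed with the deposited log2 values. Among 17 G1 regulators CDK6 was 3.37-fold higher (3.25 to 3.49) at 813 CPM, and the CDK inhibitor genes CDKN1C and CDKN1B were lower, at -3.35 and -1.17, with a median of -0.41 (percentile 0.65).

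Lineage genes differed in opposite directions. Goblet and gastrointestinal genes had 9 of 13 members lower and 3 higher, and the lowest median of all lists, -3.44 (percentile 0), which was -2.46 with at least 5 CPM and -1.48 with the deposited log2 values. The trefoil factor gene TFF1 had 832 and 8 counts, SPDEF was at least 18.2-fold and VIL1 at least 11.4-fold lower, MUC5AC was at -4.22, and AGR2, the most abundant by the mean though not in the resistant library, was 2.81-fold lower (2.71 to 2.92). The 3 higher members were MUC5B (3.16), GCNT3 (2.97) and MUC13 (2.68). VIL1 (-0.82) and MUC5AC (-0.94) did not pass with the deposited log2 values. Neuroendocrine genes were higher for 5 of 6 measured members, with a median of 2.51 (percentile 99.1), or 0.67 with the deposited log2 values. UCHL1 reached 163 CPM, while DLL3, SYT1 and NCAM1 stayed at 4.95, 1.65 and 1.47 CPM, and ENO2 was at 1.01. DLL3, SYT1 and NCAM1 were under 1 CPM in the parental library and were measured only through the resistant one, which fixed their direction. With at least 5 CPM the list had under 5 measured members and no median. SYT1 (0.41), NCAM1 (0.32) and ENO2 (0.94) did not pass with the deposited log2 values, which left 2 higher members. SYT1 and NCAM1 had deposited values under 1 in both libraries and could not pass. Squamous and basal genes had 5 lower and 2 higher of 11, with SPRR3 at -2.04 and a median of -0.24 (percentile 14.1), which was also the ratio of PERP, the most abundant, and -0.15 with at least 5 CPM. KRT6A had 24 and 2 counts, its paralog KRT6B 18 and 3, and KRT13 3 and 26. The remaining 3 were DSC3 (-1.49), IVL (-1.26) and SPRR1B (1.05). Only SPRR3 and SPRR1B passed with the deposited log2 values. Of 6 measured alveolar and club cell genes, 1 was higher and 1 lower. FOXA2, the lower one, had 19 and 0 counts (-0.58 with the deposited log2 values), and FOXA1, the most abundant, was at -0.77, with a list median of -0.13 (percentile 31.6), or -0.08 with the deposited log2 values. Among 8 stem cell associated genes NES, at 2.79 and 62.5 CPM, was higher and ALDH1A3 lower, with a median of -0.30 (percentile 7.07).

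WNT pathway genes had 5 higher and 3 lower of 13, with a median of 0.59 (percentile 95.02), which was -0.02 with at least 5 CPM and 0.30 with the deposited log2 values. The WNT inhibitor gene SFRP1 was at least 144-fold higher and WNT7A was at 2.84, with AXIN2 (1.91), NOTUM (2.14) and SP5 (1.81) the others, while NKD1 (-2.41), RNF43 (-2.16) and FZD7 (-1.13) were lower and DKK1, the most abundant, was at -0.34. With the deposited log2 values, 3 were higher and 1 lower, and NOTUM (0.56), SP5 (0.68), RNF43 (-0.996) and FZD7 (-0.80) did not pass. Hypoxia and glycolysis genes had 6 higher and 3 lower of 21, with a median of 0.17 (percentile 92.6). The glucose transporter genes went apart, with SLC2A3 25.4-fold higher (17.2 to 39.2) and SLC2A1 3.40-fold lower (3.17 to 3.66). BNIP3 was at 2.15, NDRG1 at -2.59, PFKFB3 at -1.02 (-0.95 with the deposited log2 values) and ENO1, the most abundant, at 0.22. Of 23 cholesterol synthesis genes 2 were higher, among them STARD4 (2.85), and 0 were lower. Of 12 fatty acid synthesis genes, the desaturase genes FADS1 (1.23) and FADS2 (1.34) were higher, SCD (-1.04) and PNPLA3 (-1.95, or -0.54 with the deposited log2 values) lower, and FASN, the most abundant, at -0.15. Medians were 0.08 (percentile 78.1) and -0.13 (percentile 24.8).

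Housekeeping and stress response groups had medians near 0. Ribosomal protein genes had 0 of 37 members past 2-fold and a median of 0.04 (percentile 85.3), and reference genes 0 of 14 and a median of 0.11 (percentile 83.3), with the actin gene ACTB at 0.16 and RPS2 at -0.30. The ribosomal median was 0.02 with total count scaling. Oxidative phosphorylation genes had a median of -0.08 (percentile 33.5), with COX5B (1.21) the 1 member past 2-fold and ATP5B at 0.23. Genes of the ATF4 and unfolded protein responses had a median of 0.13 (percentile 86.8), with HERPUD1 (1.25) and ASNS (1.04) higher, DDIT4 (-1.61) lower and HYOU1 at 0.94. Heat shock genes had a median of -0.08 (percentile 39.2), yet HSP90AB1, which encodes a cytosolic HSP90, was 2.78-fold higher (2.75 to 2.81) and the most abundant gene of the resistant library at 6977 CPM. HSPA1A was at -5.75 and its near-identical copy HSPA1B at -0.85, so the split of reads between these copies is uncertain.

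Markers of other cell types were mostly absent. Of 10 fibroblast markers 2 were measured, COL1A1 at 20.7 and 14.3 CPM and COL14A1 at 0 and 49 counts. Of 14 leukocyte markers 4 were measured, with CD68 (-1.44) and PTPRC (-1.53) lower and CD14 (2.60) higher. COL14A1 (0.53), PTPRC (-0.21) and CD14 (0.94) did not pass with the deposited log2 values. Of 10 endothelial markers 2 were measured, with CDH5 at 5 and 495 counts, and erythroid markers had 0 measured. Of 22 cancer-testis genes present 4 were measured, with PRAME 2.17-fold higher (1.91 to 2.46) and MAGEA3, which has close paralogs, at 4 and 215 counts.

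Neighbouring genes differed together in parts of the genome. Along the order of 12205 tested genes, 334 windows of 25 genes had a running median of 0.8 or more in size, 259 of them above 0, in 23 segments on 11 chromosomes. The stretches below run from the first to the last gene that these windows cover, so their ends reach past the centres. The longest were on chromosome X, where genes from GYG2 to RPGR had a median log2 ratio of -0.97 and a following stretch, from DYNLT3 to SMC1A, 0.85. On chromosome 8 the windows were centred on genes from ZFPM2 to RNF139 and had a median of 0.90 over all genes they cover, 83.3% of them above 0, with lower genes from FAM84B to EFR3A at the far end. On chromosome 19 the genes from DMPK to RUVBL2 had a median of 0.82, on chromosome 2 those from NCAPH to POU3F3 0.80 and on chromosome 11 those from INTS4 to MTMR2 0.79. Some higher stretches were mixed over all genes they cover. From HAT1 to GULP1 on chromosome 2, 62.2% of the genes were above 0. From MRPL2 to MUT on chromosome 6, 46.15% were, with a median of -0.23. On chromosome 12 the genes from RIMKLB to CMAS had a median of -0.69. At MET itself the running median was -0.12. The number of windows was 147 with windows of 51 genes and 707 with windows of 9 genes.

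**Figure D3:**
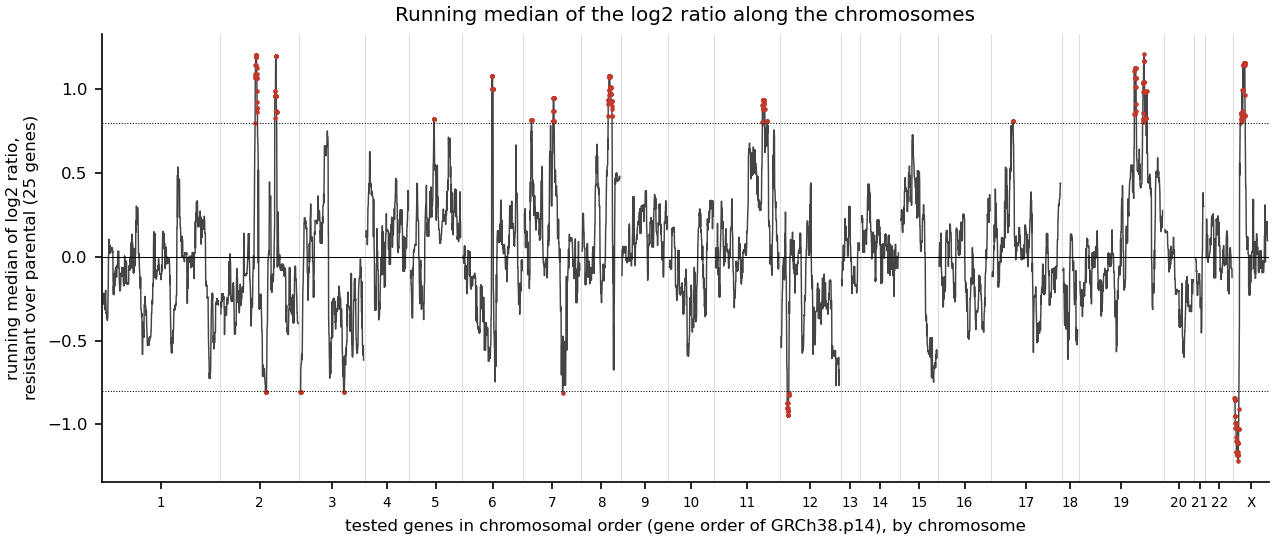
Running median of the log2 ratio (resistant over parental) over 25 consecutive tested genes, in chromosomal order from chromosome 1 to X, with dotted lines at 0.8 and -0.8. Red points are the 334 windows past those lines, and they gather in 23 segments, the longest on chromosome X with a lower stretch followed by a higher one.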

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

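The scaling changed little. Total counts, DESeq2 size factors, upper quartile factors and 2 counts added kept both counts of genes within 1.5 times. So did no filter beyond 1 count, at least 5 CPM and thinning of the deeper library. A correction for GC content and transcript length, added after the data were seen, did as well. The filter mattered more than the scaling: with at least 5 CPM, 1000 genes were higher and 748 lower, against 1480 and 1015 in the main calls. A whole interval beyond 2-fold gave 1097 genes higher and 655 lower, and 4-fold gave 774 and 359, fewer by construction. The deposited log2 values, also added later, gave 926 higher and 591 lower with a difference of 1 or more, of which 921 and 590 were shared with the main calls; the cause was not tested. Windows of 51 genes gave 147 genes at centres of windows past the threshold and windows of 9 genes, added later, 707. All 258 values of list medians under the alternatives stayed within the order-statistic interval of the main median, but these intervals are wide. The largest shifts were 1.96 with the deposited log2 values (goblet and gastrointestinal genes), 1.05 with at least 5 CPM (mesenchymal genes) and 0.425 with 2 added to each count (goblet and gastrointestinal genes), against at most 0.0202 with the other scalings; the cause was not tested. The sign differed only where the median lay near 0 or, for WNT pathway genes, with at least 5 CPM. The BCL2 family median reached or crossed 0 under 4 settings. Of 892 values for named genes under the other scalings and with 2 added to each count, 6 left the counting interval. With the deposited log2 values 116 of 223 left it, and of 151 named genes past 2-fold 26 had a difference under 1 in size. For abundant genes such as HSP90AB1 (1.48 against 1.48) and EGFR (1.20 against 1.19) this difference was close to the log2 ratio from the counts. For scarce genes such as AXL (0.66 against 2.8) and SYT1 (0.41 against 4.24) it was smaller. The cause was not tested. AXL and SYT1 had deposited values under 1 in both libraries, so a difference of 1 was out of reach for them. In all, 0 values changed the sign of a call. Percentiles moved by over 2 points with 10 bins for 4 of 37 lists. Depth limits what can be said of genes under about 0.178 CPM.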

Other observations

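Several gene families outside the fixed lists stood out after the data were seen. All 8 measured pregnancy-specific glycoprotein (PSG) genes on chromosome 19 were at least 2-fold higher in the resistant library, with a median log2 ratio of 4.79, or 3.81 with 0 counts set at their bound. PSG5 had 13 and 2568 counts and PSG4 172 and 2629, and since these genes are near-identical, the split among them is uncertain. PSG5 and the PSG genes with 0 parental counts were measured only through the resistant library, so the filter fixed their direction. Of 9 measured aldo-keto reductase genes 7 were higher, with AKR1B1 at 2089 and 11170 counts. Among genes of insulin-like growth factor binding proteins 6 of 7 were higher (4 with the deposited log2 values), and IGFBP2 was 7.34-fold lower (6.63 to 8.14). Of 25 measured collagen chain genes 13 were higher and 6 lower, or 11 and 2 with the deposited log2 values.

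On chromosome 11, CASP4 was higher at 81.2 and 568 CPM, as were CASP1 at 0 and 204 counts and CARD16, a close paralog of CASP1, at 1 and 242. All 5 measured HOXD genes on chromosome 2 were higher (4 with the deposited log2 values), HOXD8 from 13 to 503 counts and HOXD4 from 0 to 125. HOXD8 and HOXD4 were under 1 CPM in the parental library and were measured only through the resistant one. The filter thus fixed the direction of HOXD8 and HOXD4, though not the size of the difference. Of the other families 3 of 11 HOXA, 1 of 7 HOXB and 2 of 6 HOXC genes were higher. The HOXD genes lie directly before the block of neighbouring genes from MTX2 to RBM45, all 6 of which had ratios above 0. The 10 genes before that block, HOXD genes among them, had a median of 3.06 and the 10 after it -0.10.

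Some neighbouring genes formed blocks with sharp edges, picked after they were seen. On chromosome 8 all 8 tested genes from FAM84B to ST3GAL1 were lower (median -2.55), among them FAM49B, ASAP1 and EFR3A at 5.35-fold, 5.72-fold and 6.01-fold, with MYC at 1.75-fold, while the 10 genes before the block had a median of 0.63 and the 10 after it -0.05. On chromosome 3 all 5 from VGLL3 to C3orf38 were higher (median 1.95), between flanks at -0.79 and -0.50, and on chromosome 6 all 12 from POLH to AARS2, which include HSP90AB1 and VEGFA, were higher (median 1.30), between flanks at -0.36 and -0.83. Of 12 tested genes around MET 10 had ratios below 0 (median -0.78), between flanks at -0.18 and -0.10. Only 3 of the 12 were at least 2-fold lower, and 2 were at least 2-fold higher.

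The tests below were all chosen after the results were seen.

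Genes silent in one library and abundant in the other, 34 in all, set the libraries apart. Fibroblasts mixed into the resistant library are argued against, since the median fibroblast marker stood at 0.118 CPM there beside 322 CPM for VIM, and added cells would not remove transcripts such as DIAPH2, whose 0 counts allow at most 0.487% of the parental level. A library from an unrelated line cannot be told apart from a diverged derivative, because MET ranked 6 in the resistant library, as a descendant or another MET-amplified line could show, and no genotype is available. Selection in drug, which the design names, and drug present at harvest remain open and untested.

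Runs of neighbouring genes that differ together had 334 genes at the centres of their windows. Chance order of the genes is argued against, as the highest of 100 shuffled orders gave 10 such genes. Trends with GC content and transcript length are argued against, as 352 genes lay at such centres once both were removed. DNA copy number is a candidate explanation that RNA alone cannot decide: 92.5% of the genes at the centres shared the direction of their run, which the way runs were picked largely fixes.

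The gene of NRF2 itself, NFE2L2, was 3.98-fold higher (3.72 to 4.26). Of 24 measured NRF2 target genes 13 were also higher, while 10, among them GCLC (0.10) and GCLM (0.15), passed neither way. Reads shared among AKR1 paralogs are argued against as the source of the higher list median, since the 20 other members kept a median of 0.91 (order-statistic interval 0.39 to 1.92). Low KEAP1 mRNA, the mRNA of the NRF2 repressor, is argued against by a KEAP1 log2 ratio of 0.17, though a KEAP1 mutation would not show here. NFE2L2 lies in a block on chromosome 2 whose 5 other tested genes, from MTX2 to RBM45, had a median log2 ratio of 1.45. The block was picked after its ratios were seen, which largely fixed this median in advance. Over the wider run of windows there, from HAT1 to GULP1, the median was 0.51, with 62.2% of the genes above 0. Whether the higher NFE2L2 level is regional or specific to that gene therefore cannot be decided here. The hypothesis that a gained NFE2L2 region feeds the NRF2 targets needs DNA data and remains untested.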
